A study of Homo sapiens with 12 samples.

How the data were processed

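RNA was sequenced from primary human intestinal myofibroblasts, the contractile and matrix-producing stromal cells of the gut wall, grown from normal colon and used at passages 8 to 10. The cells were left untreated or given purified flagellin, the bacterial flagellum protein that Toll-like receptor 5 recognises, and were collected at 1 h or 24 h. There were 3 libraries in each of the 4 groups, 12 in all, read as 50 bp single-end reads. The labels of the libraries gave the group and the replicate number, and nothing in them said whether the replicates of a group came from separate cultures. The p-values therefore measure the spread between these libraries, part of which may be technical.

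The deposited files for each library hold read counts per gene, made by the authors with STAR's gene counting, which takes uniquely mapped reads only. Per the submitters' processing notes, reads went through Trim Galore 0.3.7 and FastQC 0.11.3 and were aligned with STAR 2.5.3a to the GRCh38 build. Each file gives an unstranded count and a count for each strand. The total over genes of the reverse-strand column was at least 23.9 times that of the forward column in every library, above the minimum of 5 times fixed beforehand, so the reverse-strand counts were used and the unstranded counts were an alternative. Because only unique reads were counted, genes with near-identical copies lose reads, and their values are uncertain. The 4 summary lines of each file, which name no gene, were left out of library sizes and tests. They held unmapped reads (0.776% to 1.16% of all reads), multimapping reads (12.9% to 16.6%), reads outside genes (8.04% to 21.3%) and ambiguous reads (3.18% to 5.50%).

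The files list 58288 genes. Of these, 58025 were named from GENCODE release 29, which is on the same build, and the other 263 stayed without a symbol. The 563 genes on chromosome Y together with XIST were removed before any test, which left 57725. Coordinates are on GRCh38 from that annotation. One further table of the whole series holds log2 fold changes, their standard errors, p-values and adjusted p-values which, per the title lines of the authors' deposited table, came from DESeq2 with a term for the source of the cells, at a time point the table does not state. A further 24 columns of per-sample values in that table were not used here, since their names give no time point or replicate number and match no single library.

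Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, libraries were scaled by TMM, and quasi-likelihood models (glmQLFit with robust settings, glmQLFTest) with 1 mean per group were fitted to all 12 libraries, which leaves 8 residual degrees of freedom. Each gene thus has 1 estimate of spread over all groups. Standard errors, p-values and lost calls at 24 h therefore also carry spread between libraries of 1 h. In all, 16188 genes were tested. Benjamini-Hochberg adjustment was applied over all genes tested, and a gene was called at an adjusted p below 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Expression is given as CPM, reads of a gene scaled to a common library total, computed from the deposited counts with TMM-scaled library sizes, as mean ± SD over 3 libraries. The comparisons were flagellin against untreated at each time, the difference between these effects, and untreated libraries at 24 h against those at 1 h. Where a group had no reads of a gene, the fold was bounded with 3 counts over the group. Such bounds, and the 95% intervals of read ratios, cover counting error only.

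Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, for lists with at least 5 tested members, with adjustment over the lists. Each test was repeated with camera's estimated correlation and with fry. Before the data were examined, 26 lists, 19 single genes, the tests, the alternatives and the rule for named genes were fixed. The rule takes the 19 genes, the 12 called genes with the highest and the 12 with the lowest log2 fold change among those with a symbol and a mean of at least 1 CPM at that time, or the 10 with the smallest p where fewer than 10 were called, and up to 4 members of each list with the smallest p. It takes the 6 highest and 6 lowest called genes for the difference between times, and likewise for untreated libraries with the same minimum level. A list of HOX genes was added after the data had been seen.

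The models were tested on simulated counts drawn from the real means, dispersions and library sizes, in which 200 genes were changed at each time. For flagellin against untreated at 1 h, over 15909 simulated genes, 52.2% of genes changed 2-fold and 95.5% of those changed 4-fold were recovered, and 13.4% of those changed 1.5-fold. With a replicate block these shares were 86.6%, 100% and 65.7%, with 18 unchanged genes called against 0 without the block. For flagellin against untreated at 24 h the model without the block recovered 17.9%, 55.2% and 92.4% of genes changed 1.5-fold, 2-fold and 4-fold.

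Replicate numbers are shared between groups, so it was checked whether they pair the libraries. At 1 h, deviations from the group mean correlated between untreated and flagellin libraries of the same number at 0.651, 0.704 and 0.695 across genes. By these correlations the numbers pair the libraries at 1 h. Every pair of unlike numbers correlated negatively, which centring each group on its mean favours and which is no separate support. At 24 h the same correlations were 0.0779, -0.136 and -0.108, and the numbers do not pair the libraries. Alternatives were other scalings and count filters, DESeq2 1.42.0, limma-voom, a fit of the libraries of the comparison alone, a replicate block, unstranded counts, an adjusted p below 0.01, a test against a fold change of 1.2 (glmTreat), and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9.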

Results

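Gene expression was measured by RNA sequencing in human intestinal myofibroblasts that were untreated or exposed to flagellin for 1 h or 24 h, with 3 libraries in each group. Reads assigned to genes ranged from 17702972 to 22402037 per library. Libraries of 1 h held 20938690 reads or more, and those of 24 h held 19924253 or fewer. Uniquely mapped reads lying outside annotated genes made up 9.53% to 15.3% at 1 h and 19.2% to 25.2% at 24 h. The first principal component of log2 CPM, with 52.7% of the variance, parted the times, and the second, with 20.6%, parted untreated from flagellin libraries at 24 h.

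**Figure D1:**
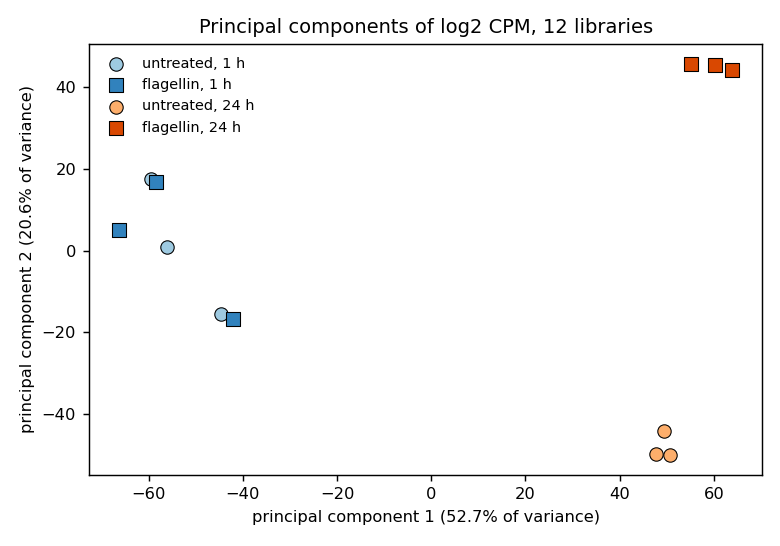
Principal component 1 (horizontal, 52.7% of variance) against principal component 2 (vertical, 20.6% of variance) of log2 CPM, with 1 point per library, circles for untreated and squares for flagellin. The 6 libraries of 1 h lie together at the left with untreated and flagellin mixed, and the libraries of 24 h form separate untreated and flagellin clusters.

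Flagellin for 1 h, which asks for the early response of these cells, changed no gene past the threshold. NFKBIA, the inhibitor of NF-kB that is itself an NF-kB target, was at 27.2 ± 3.59 CPM (SD, n = 3) untreated and 29.9 ± 0.787 CPM with flagellin. The chemokine CXCL8 was at 0.280 ± 0.0965 and 0.326 ± 0.255 CPM, and the cytokine IL6 at 5.19 ± 3.27 and 5.75 ± 3.06 CPM. TLR5, the flagellin receptor (ENSG00000187554.11, chromosome 1, 223109406 to 223143282, minus strand), was at 1.67 ± 0.211 and 1.14 ± 0.518 CPM, and its adaptor MYD88 was at 14.7 ± 2.77 and 10.4 ± 2.16 CPM. The immediate early gene FOS had a log2 fold change of 0.54 ± 0.29 (SE), and EGR1 one of -0.36 ± 0.49. Among matrix genes, FN1, which encodes fibronectin, was at 8076 ± 1759 and 7135 ± 1281 CPM, and the type I collagen gene COL1A1 at 2011 ± 23.2 and 1692 ± 528 CPM. None of these differences passed the edgeR test (adjusted p = 1 for each). Within the 3 numbered pairs of libraries, compared after seeing the data, FOS and CXCL1 were higher with flagellin in all 3, and MYD88, TLR5, EGR1, FN1 and COL3A1 were lower in all 3. With the replicate block FOS had a log2 fold change of 0.58 ± 0.17 (SE) and MYD88 one of -0.49 ± 0.14 (edgeR adjusted p = 0.630 for both), and TLR5 one of -0.58 ± 0.27 (edgeR adjusted p = 0.854). The sign was the same in all 3 pairs for 27.4% of the 16188 genes tested, where chance gives 25%.

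By edgeR's quasi-likelihood test, 0 of 16188 genes were called at 1 h, and 299 genes (1.85%) had an unadjusted p below 0.05, of which 69 were higher and 230 lower. DESeq2 and limma-voom with the same design also called 0 genes, and so did edgeR with the replicate block, where 932 genes had an unadjusted p below 0.05. DESeq2 with the replicate block on the libraries of 1 h alone, an analysis chosen after seeing the data, called 4 genes. All were lower with flagellin: ZMIZ1, and NFIC, NFIX and EHD2, which were named after their values were seen. NFIC had the smallest adjusted p of these, 0.000127 by DESeq2, at a log2 fold change of -0.70 ± 0.12 (SE). The authors' deposited table of flagellin against untreated does not state its time point, and 0 of its 17365 genes had an adjusted p below 0.05, with a smallest adjusted p of 0.388. An unadjusted p below 0.05 was listed for 931 genes in the authors' deposited table, and the first by p were LDOC1, TIMP2 and EPHX1, with log2 fold changes of -0.30, -0.27 and -0.28. All log2 fold changes there lay between -0.304 and 0.279, a narrower range than that of the estimates made here. Their sizes are therefore not comparable with those given here. Across 15664 genes in both sources, log2 fold changes in the authors' deposited table correlated at 0.668 with those computed here at 1 h, and genes are not independent replicates. The sign was the same for 94.3% of these genes, so the 0 calls there may not be separate from the result at 1 h.

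Camera with the preset correlation called 5 of the lists at 1 h although no single member was called, with adjustment over all genes or adjusted over the list alone. Cytosolic ribosomal proteins (72 tested, median log2 fold change 0.09, adjusted p = 1.0e-07) and cell cycle genes (36 tested, median 0.20, adjusted p = 0.0040) ranked higher than other genes. Mitochondrially encoded genes (13 tested, median -0.57, adjusted p = 9.4e-05), collagens (21 tested, median -0.05, adjusted p = 0.036) and other matrix proteins (48 tested, median -0.08, adjusted p = 0.012) ranked lower. With an estimated correlation none of the 5 was called: the adjusted p = 0.455 for other matrix proteins and adjusted p = 0.937 for the other 4. Fry called none of them. With the replicate block, camera with the preset correlation called the same 5 lists in the same directions. The camera adjusted p was 3.0e-12 for cell cycle genes, 2.0e-06 for cytosolic ribosomal proteins and 0.000508 for mitochondrially encoded genes. It was 0.00285 for other matrix proteins and 0.0091 for collagens. In tests chosen after seeing the data, camera with an estimated correlation (adjusted p = 0.983 for each) and fry called none with the replicate block. Untreated replicate 1 stood apart for mitochondrial reads, at 0.444% of the total against 0.196% to 0.281% in the other 5 libraries of 1 h. Without it the median of the mitochondrially encoded list was -0.13 (camera adjusted p = 0.745), that list and the collagens (camera adjusted p = 0.374) were not called, and the count of lists was 3. The mitochondrially encoded list was not called without flagellin replicate 3 either (camera adjusted p = 0.0610). The count was also 3 without flagellin replicate 2, where the median of the collagens was 0.11 (camera adjusted p = 0.723) and other matrix proteins were not called (camera adjusted p = 0.114). The collagens also lost their call without untreated replicate 2 or 3 (camera adjusted p = 0.0814 and 0.0545), and other matrix proteins without untreated replicate 2, untreated replicate 3 or flagellin replicate 3 (camera adjusted p = 0.184, 0.0579 and 0.0754). The cell cycle list ranked lower without untreated replicate 2 (median -0.15, camera adjusted p = 0.0369) and was not called without flagellin replicate 1 (camera adjusted p = 0.411) or flagellin replicate 3 (median -0.16, although camera ranked it higher, adjusted p = 0.999). Of the 5 lists, cytosolic ribosomal proteins alone kept their call, as higher, whichever library of 1 h was left out (highest camera adjusted p = 0.0129). The fits that left out a library had no replicate block. The list of NF-kB pathway and feedback genes (29 tested, median 0.01, camera adjusted p = 0.884) and that of chemokines (12 tested, median 0.12, camera adjusted p = 0.870) were not called.

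At 24 h, which asks for the later state of the cells, flagellin libraries held more mRNA of contractile genes and less of fibroblast and matrix genes than untreated libraries. ACTA2, the smooth muscle actin that marks myofibroblasts (ENSG00000107796.13, chromosome 10, 88935074 to 88991339, minus strand), was at 1049 ± 41.6 CPM untreated and 3889 ± 101 CPM with flagellin, a 3.71-fold rise (log2 1.89 ± 0.27 SE, edgeR adjusted p = 0.000447). PDGFRA, a growth factor receptor of fibroblasts (chromosome 4, 54229097 to 54298247, plus strand), was at 898 ± 89.1 and 199 ± 9.40 CPM, 4.51-fold lower (log2 -2.17 ± 0.11, edgeR adjusted p = 3.1e-07). Collagen mRNAs COL1A1, COL1A2 and COL3A1 were lower as well, while FN1 was at 6758 ± 217 and 6978 ± 804 CPM and not called (edgeR adjusted p = 0.881). In all, 3816 of 16188 genes were called, 2056 higher and 1760 lower, and of these 734 and 751 differed more than 2-fold.

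**Figure D2:**
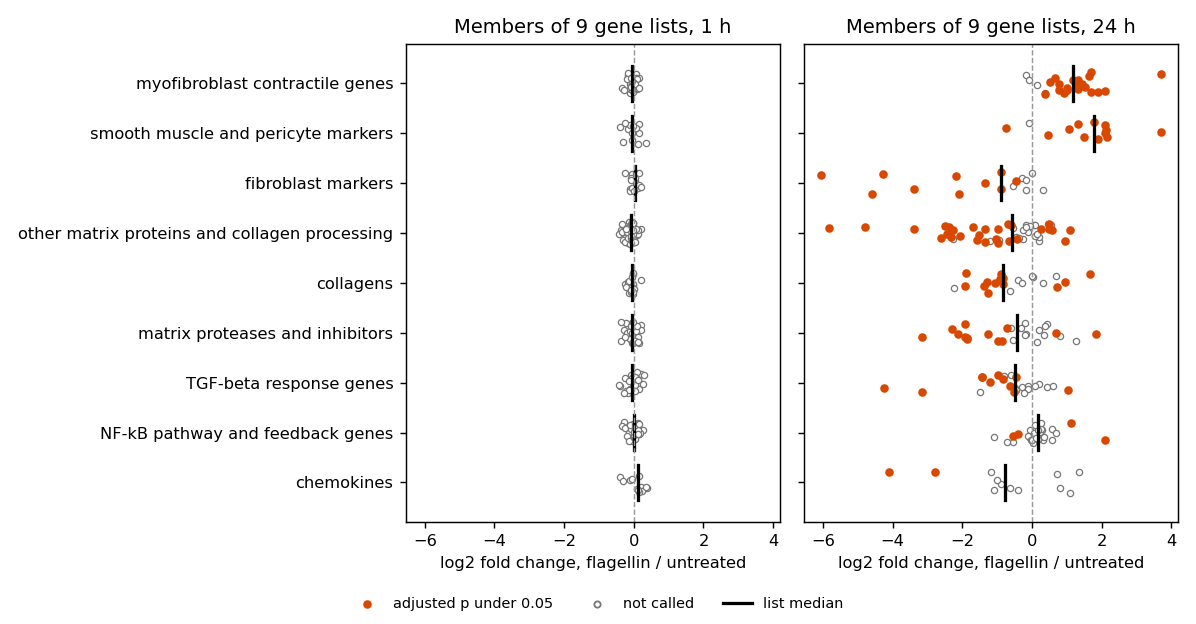
Log2 fold change of flagellin over untreated (horizontal) for each tested member of 9 gene lists (rows) at 1 h (left) and 24 h (right). Filled points are genes with adjusted p below 0.05, open points are not called, and vertical bars are list medians. No member is filled at 1 h, and at 24 h 21 of 25 contractile genes are filled to the right of 0.

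Of 25 myofibroblast contractile genes, 21 rose at 24 h and none fell, also when adjusted over the list alone (camera adjusted p = 9.85e-12, and adjusted p = 0.131 with an estimated correlation). PALLD, an actin-bundling protein, was 3.09-fold higher, the actin-binding SYNPO2 3.22-fold, the myosin light chain kinase MYLK 2.51-fold and the tropomyosin TPM4 1.89-fold. Of 13 smooth muscle and pericyte markers, which share 3 genes with the contractile list, 11 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 3.39e-06, and adjusted p = 0.0585 with an estimated correlation). MCAM rose from 129 ± 8.87 to 563 ± 10.1 CPM, the potassium channel gene KCNJ8 from 5.17 ± 0.543 to 17.8 ± 1.18 CPM, its partner subunit ABCC9 from 11.3 ± 0.936 to 50.2 ± 10.9 CPM, and RGS5 from 9.63 ± 2.98 to 41.4 ± 9.30 CPM. Under upper-quartile scaling 10 members of that list rose and 1 fell.

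Of 16 fibroblast markers, 10 fell and none rose (11 fell when adjusted over the list alone; camera adjusted p = 3.7e-06, and adjusted p = 0.0144 with an estimated correlation). MFAP5, a microfibril protein, was 10.4-fold lower, S100A4 4.26-fold and the proteoglycan LUM 2.57-fold. Of 48 other matrix proteins and collagen-processing genes, which share 3 genes with the fibroblast list, 22 fell and 6 rose (26 and 6 adjusted over the list alone; camera adjusted p = 8.8e-06, and adjusted p = 0.0220 with an estimated correlation). MFAP4 was 6.11-fold lower, the collagen cross-linking enzyme LOXL3 4.78-fold and the fibrillin FBN1 2.57-fold. Of 21 collagens, 10 fell and 3 rose (11 and 4 adjusted over the list alone; camera adjusted p = 0.00921, and adjusted p = 0.470 with an estimated correlation). COL6A3 was at 2036 ± 136 CPM untreated and 549 ± 20.6 CPM with flagellin, and COL14A1 at 3767 ± 58.5 and 1461 ± 127 CPM. COL4A1, a basement membrane collagen, rose from 957 ± 58.9 to 1827 ± 280 CPM. COL14A1 had 20596 to 33304 reads per library at 1 h, 70167 to 71444 untreated and 25062 to 30383 with flagellin at 24 h. Its untreated libraries of 24 h thus lay above those of 1 h, and the flagellin ones among them. LUM had a like pattern. COL6A3 had 36740 to 68669 reads at 1 h and 9129 to 10841 with flagellin at 24 h.

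Of 26 matrix proteases and inhibitors, 11 fell and 2 rose, also when adjusted over the list alone (camera adjusted p = 0.0150, and adjusted p = 0.0801 with an estimated correlation). The collagenase MMP1 was 4.38-fold lower, the gelatinase MMP2 3.64-fold and the inhibitor TIMP3 3.76-fold, while TIMP1 was 1.61-fold higher. MMP3 was at 40.8 ± 6.08 and 54.5 ± 0.634 CPM and not called. Of 24 TGF-beta response genes, 10 fell and 1 rose (11 and 2 adjusted over the list alone; camera adjusted p = 0.00090, and adjusted p = 0.0801 with an estimated correlation), with COMP 19.1-fold, ID2 2.73-fold, SNAI2 1.99-fold and the decoy receptor BAMBI 1.77-fold lower.

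Genes of flagellin signalling and inflammation were called in both directions at 24 h. TLR5 was at 1.76 ± 0.440 CPM untreated and 0.394 ± 0.251 CPM with flagellin, 4.39-fold lower (log2 -2.13 ± 0.44 SE, edgeR adjusted p = 0.00478), and TLR4 was 4.06-fold lower (edgeR adjusted p = 0.0103). Of 27 Toll-like receptor signalling components, 3 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.335). Of 29 NF-kB pathway and feedback genes, 2 rose and 2 fell (1 and 1 adjusted over the list alone), with a median log2 fold change of 0.16 (camera adjusted p = 0.439), and NFKBIA was at 45.0 ± 24.6 and 43.1 ± 28.0 CPM. In 1 library of each group NFKBIA stood apart, at 73.4 CPM in untreated replicate 3 and 75.5 CPM in flagellin replicate 2, against 25.9 to 31.6 CPM in the other 4, and IL6 and ICAM1 were highest of their group in the same libraries. Without untreated replicate 3 the NF-kB list was called higher by camera (median 0.33, adjusted p = 0.0235, and adjusted p = 0.649 with an estimated correlation), and without flagellin replicate 2 its median was -0.05 (camera adjusted p = 0.714). None of its members was called without untreated replicate 1 or without untreated replicate 2. The adhesion molecule ICAM1 rose from 32.5 ± 24.9 to 139 ± 76.7 CPM (log2 2.10 ± 0.56, edgeR adjusted p = 0.0201). Its call was lost without untreated replicate 1, untreated replicate 2 or flagellin replicate 2 of 24 h, with edgeR adjusted p of 0.0808, 0.0841 and 0.0815. Of 12 chemokines, 2 fell and none rose, also when adjusted over the list alone (camera adjusted p = 0.164): CCL13 was 17.1-fold and CCL11 6.83-fold lower. The CCL11 call was lost in 6 of 12 fits that left out 1 library (highest edgeR adjusted p = 0.120). CCL11 had 1847 to 2305 reads in untreated and 217 to 365 in flagellin libraries of 24 h. At 1 h it ranged from 178 to 1415 reads per library, and that spread enters its test at 24 h. CCL2 was at 114 ± 29.1 and 60.7 ± 48.5 CPM and not called, and without flagellin replicate 2 of 24 h its edgeR adjusted p was 0.00394. Of 31 cytokines and growth factors, 2 rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.439), among them IL33, an alarmin of the IL-1 family, 6.23-fold lower, WNT5A 2.83-fold lower and IL15 2.09-fold higher. IL6 and CXCL8 were not called (edgeR adjusted p = 0.283 and 0.104).

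**Figure D3:**
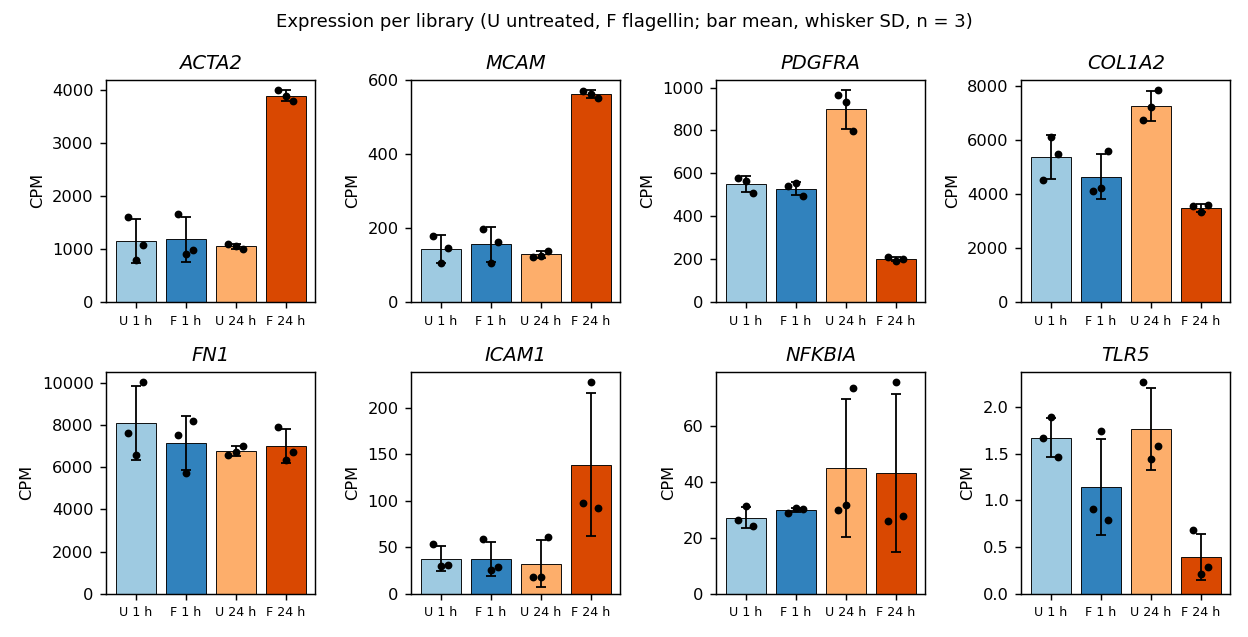
CPM (vertical, from 0) of 8 genes in untreated (U) and flagellin (F) libraries at 1 h and 24 h. Bars are means, whiskers are SD and points are the 3 libraries of each group. ACTA2 and MCAM are highest and PDGFRA and COL1A2 lowest in flagellin libraries of 24 h, while FN1 and NFKBIA overlap between the groups.

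A further 4 lists at 24 h were called by camera with the preset correlation and not by fry. Of 34 interferon-stimulated genes 7 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.0183, and adjusted p = 0.725 with an estimated correlation). IFI6 was 3.23-fold higher, a call lost without untreated replicate 2 or flagellin replicate 2 of 24 h (edgeR adjusted p = 0.0740 and 0.0563), and the calls of TAP1, GBP2 and GBP1 were lost in 2, 2 and 3 of 12 such fits. Without flagellin replicate 2 the interferon list had 1 higher and 1 lower member and a median of -0.05 (camera adjusted p = 0.789). With untreated replicate 1 left out 2 members rose, and with untreated replicate 2 left out none did. Of 24 cholesterol synthesis genes 4 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.00591, and adjusted p = 0.712 with an estimated correlation). Of 13 mitochondrially encoded genes 3 rose, also when adjusted over the list alone (camera adjusted p = 0.0183, and adjusted p = 0.712 with an estimated correlation). MT-CO1, a subunit of cytochrome c oxidase, was 2.26-fold higher, and mitochondrial reads were 0.158% ± 0.0149 of the total untreated and 0.318% ± 0.0593 with flagellin. Of 72 cytosolic ribosomal proteins 6 fell and 1 rose (4 and 1 adjusted over the list alone), and 12 fell under upper-quartile scaling (camera adjusted p = 0.0183, and adjusted p = 0.719 with an estimated correlation). Lists not called held immediate early genes (8 of 35 higher, 4 lower, or 9 and 4 adjusted over the list alone), hypoxia and glycolysis genes (7 of 29 higher, 2 lower, or 10 and 3 adjusted over the list alone), unfolded protein response genes (1 of 22 higher, 6 lower), prostaglandin and oxidative defence genes (3 of 20 higher, 2 lower), translation factors (0 of 37 higher, 4 lower, or 3 lower adjusted over the list alone) and cell cycle genes (1 of 36 higher, and 0 adjusted over the list alone). None of 6 tested endothelial, 4 leukocyte or 4 glial and neuronal markers was called, and of 2 epithelial markers KRT8 fell from 0.995 ± 0.206 to 0.126 ± 0.0269 CPM. The 1 tested mesothelial marker, PKHD1L1, was called higher, from 0.124 ± 0.0795 to 1.68 ± 0.898 CPM.

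The genes with the most extreme folds at 24 h were on in one group and nearly absent from the other. RBM46, an RNA-binding protein of germ cells, had 772 reads in the untreated libraries together and 0 in the flagellin libraries, at least 252-fold lower. ISL1, a homeodomain transcription factor, had 369 and 0 reads, at least 121-fold lower, and GTSF1 177 and 0 reads, at least 57.9-fold lower. HOXA13, a homeobox gene of the hindgut and limb ends (chromosome 7, 27193503 to 27200106, minus strand), had 985 reads and 1 read, a ratio of 966 with a 95% counting interval of 173 to 38199. DPT was at 30.6 ± 1.93 and 0.456 ± 0.129 CPM. In the other direction RELN, which encodes the secreted protein reelin, was at 0.462 ± 0.0267 CPM untreated and 96.5 ± 5.41 CPM with flagellin (log2 7.69 ± 0.99, edgeR adjusted p = 0.000336), and the retinoic acid receptor gene RARB was 28.7-fold higher. At 1 h RELN was at 20.1 ± 15.2 and 18.5 ± 13.4 CPM and HOXA13 at 8.47 ± 3.69 and 8.94 ± 3.28 CPM, neither called. The count of 3816 fell to 2372 without untreated replicate 1 and to 2261 without untreated replicate 2 of 24 h. It was 6707 when the libraries of 24 h were fitted alone, 2147 when tested against a fold change of 1.2 and 1932 at an adjusted p below 0.01.

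The flagellin effect at 24 h differed from that at 1 h for 1618 genes, 949 with a higher and 669 with a lower log2 fold change at 24 h. The flagellin effect was higher at 24 h than at 1 h for contractile genes (18 of 25 higher, 19 adjusted over the list alone, none lower). The same held for smooth muscle and pericyte markers (8 of 13 higher, 10 adjusted over the list alone, none lower). It was lower for fibroblast markers (7 of 16 lower, 9 adjusted over the list alone, none higher) and other matrix proteins (18 of 48 lower and 3 higher, 19 and 6 adjusted over the list alone). Camera called all 4 (adjusted p = 1.6e-12, 5.3e-07, 6.2e-06 and 0.00012), and with an estimated correlation adjusted p = 0.115, 0.0418, 0.0163 and 0.0418. These are differences between 2 effects, not levels against 1 h. In untreated libraries 12 of the 25 contractile genes were lower and 2 higher at 24 h than at 1 h (median log2 fold change -0.446). RELN had a difference of 7.80 ± 1.19 on the log2 scale (edgeR adjusted p = 0.00277) and HOXA13 one of -9.56 ± 0.82, which rests on 1 read in the flagellin libraries of 24 h. The count fell to 796 without untreated replicate 1, 783 without untreated replicate 2, 883 without flagellin replicate 1 and 888 without flagellin replicate 3 of 24 h. It was 902 against a fold change of 1.2 and 523 at an adjusted p below 0.01. With the replicate block within each time point the count was 4102, where the numbers pair the libraries at 1 h and not at 24 h.

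Untreated libraries of 24 h and 1 h differed for 7586 genes, 3628 higher and 3958 lower at 24 h. Of 36 cell cycle genes, 34 were lower at 24 h, also when adjusted over the list alone (camera adjusted p = 1.4e-11, and adjusted p = 0.621 with an estimated correlation). The proliferation marker MKI67 was at 141 ± 101 CPM at 1 h and 1.53 ± 0.200 CPM at 24 h, and UBE2C, a ubiquitin-conjugating enzyme of mitosis, was 99.9-fold lower. Of 35 immediate early genes, 23 were lower, 24 adjusted over the list alone (camera adjusted p = 1.4e-05, and adjusted p = 0.530 with an estimated correlation). RBM46 had 0 reads at 1 h and 772 at 24 h, and TSHR, the thyrotropin receptor gene, 1 and 493 reads, a ratio of 565 with a 95% counting interval of 101 to 22370. The share of unique reads outside genes was higher in all libraries of 24 h than in all of 1 h. At an adjusted p below 0.01 the count was 4997.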

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

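The tests of HOX genes, of NF-kB genes and of reads outside genes, the fit with DESeq2 and the replicate block, and the use of the planned replicate block as a test of hidden spread at 1 h, were chosen after the results had been seen.

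The flagellin effect differed between 24 h and 1 h, by a test of the difference itself, for 1618 genes. The 6 lowest log2 differences were those of ISL1 (-9.68), HOXA13 (-9.56), AC010478.1 (-9.48), WDR45BP1 (-7.43), OMD (-7.39) and ANKRD30B (-7.29). The 6 highest were those of RELN (7.80), GADL1 (6.57), AL592494.2 (5.96), ADD2 (5.75), MTCO1P12 (5.69) and ZG16B (5.54). Apart from RELN and MTCO1P12, each of these genes had at most 2 reads in all 3 libraries together of at least 1 group, so the fitted differences depend on the prior count and are no bounds. MTCO1P12 is a near-copy of a mitochondrial gene, and its reads are uncertain. Calls were lost in some of the 12 fits that left out 1 library for ADD2 (highest edgeR adjusted p = 0.0608), AL592494.2 (0.0501), ANKRD30B (0.0975), GADL1 (0.113), OMD (0.0746) and ZG16B (0.107). Among 100 splits of the libraries within each time, the real one included, 5 gave at least 1618 genes, and the highest other count was 3517. All 5 were among the 8 splits that left the groups of 24 h whole, which keep the effect at 24 h, and the 92 splits that mixed those groups gave 0 genes. The share as large is thus set mainly by how often the groups of 24 h stay whole, and it does not decide whether chance gives such a count.

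For the first pattern, the 3816 genes called at 24 h, thinning every library to the lowest total gave a count of 3765. Libraries of 24 h held 17702972 to 19924253 reads, so the thinning took few reads away. It argues against unequal depth between libraries only. After the trend on GC content, transcript length and level was subtracted, 89.8% of the called genes stayed past the smallest test statistic of the calls, which argues against that trend. The 9 other splits of the 6 libraries gave at most 0 genes against 3816 for the real one, 1 of 10 splits as large, and 10 splits are too few for a share below 0.05. What stays open is whether the untreated and flagellin libraries of 24 h came from different source cultures, a question that the spread raises. Libraries of 24 h varied within their groups by 9.46% (biological coefficient of variation, 1 value over both groups). Libraries of 1 h varied by 24.9% without and 9.55% with the replicate block. The 3 libraries of each group of 24 h may thus be repeats of the same culture. In that case the p-values at 24 h would not cover spread between cultures. The HOX test missed its bound, with a median absolute log2 fold change of 0.587 over 23 HOX genes, inside the central 95% of expression-matched random lists (0.217 to 0.619), but the list was picked after HOXA13 had been seen and the rule for reading the test was changed after its value was known, so it decides nothing and different cultures cannot be told apart from a flagellin effect.

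The second pattern is the lack of calls at 1 h. If spread between the numbered pairs of libraries had hidden a response, the fit with the replicate block would call genes. It called 0 with edgeR, and DESeq2 with the replicate block on the libraries of 1 h called 4. With the block in edgeR, genes with an unadjusted p below 0.05 went from 299 to 932. In simulated counts the block recovered 100% of 4-fold changes but 65.7% of 1.5-fold changes. The test was also chosen after the results had been seen, so it does not decide whether that spread hid a modest response. All 10 of the 10 splits gave at least the real count of 0, so the splits cannot bear on the lack of calls at 1 h. The 3 other splits that parted every same-numbered pair gave 0, as the real one did. Of the 6 splits that left 2 of the 3 pairs together, 1 gave 1009 genes, which points to a structure of the libraries, 1 gave 19 and 4 gave 0.

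The third pattern is the 7586 genes that differed between untreated libraries of the 2 times. The lowest share of unique reads outside genes at 24 h lay 3.87 percentage points above the highest at 1 h. Separate library sets for the 2 times may therefore have contributed, but the labels name no library batch. Such sets could not be told apart from time. Different source cultures for the 2 times could not be told apart from time either, since no label ties a library to a source. The other splits gave at most 0 genes, 1 of 10 splits as large as the real one, and 10 splits are too few for a share below 0.05.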

How the results depend on the processing

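Fits with the replicate block on the libraries of 1 h, list tests with an estimated correlation or fry in the replicate block, and fits without genes that differ between the numbered pairs of 1 h were chosen after seeing the data. At 1 h the count of called genes was 0 under every alternative chosen before the data were examined, including the replicate block within each time point, and in all 12 fits that left out 1 library. DESeq2 with the replicate block on the libraries of 1 h called 4. At 24 h the main count of 3816 became 6707 with only the libraries of 24 h and 6309 with the replicate block within each time point, where the numbers do not pair the libraries. It became 2147 against a fold change of 1.2 and 1932 at an adjusted p below 0.01, and ranged from 2261 to 4663 when 1 library was left out. The difference between times went from 1618 to 4102 with the replicate block, 902 against a fold change of 1.2 and 523 at an adjusted p below 0.01, and ranged from 783 to 1690 when 1 library was left out. Untreated libraries of 24 h against 1 h gave 4997 instead of 7586 at an adjusted p below 0.01. Gene lists called by camera at 1 h stayed at 5 with the replicate block and the preset correlation. They went from 5 to 0 with an estimated correlation and 0 with fry, each also 0 with the replicate block. They ranged from 3 to 6 when 1 library was left out of the fit without the block. At 24 h they went from 11 to 2 with an estimated correlation and 7 with fry. The replicate block gave 12 with camera, 0 with an estimated correlation and 7 with fry. The fit of the libraries of 24 h alone leaves spread between libraries of 1 h out of its estimate of spread. The replicate block within each time point leaves out spread between the numbered pairs. Libraries of 1 h varied by 24.9% without and 9.55% with the block (biological coefficient of variation), and those of 24 h by 9.46% without it. Apart from the stricter threshold and the larger minimum fold, which call fewer genes by construction, the cause of the changed counts was not tested. No called gene changed sign under DESeq2 size factors or upper-quartile scaling. With unstranded counts 7 called genes changed sign at 24 h, 3 for the difference and 29 for untreated libraries, and the higher share at 24 h went from 53.9% to 46.0% with upper-quartile scaling, and that of untreated libraries of 24 h against 1 h from 47.82% to 55.03%. Of 138 genes named for 24 h, 28 changed their call in some fit that left out 1 library. Depth limits genes of few reads, such as CXCL8 and TLR5.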

Other observations

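The tests of HOX genes, of the distances between libraries, of genes that differ between the numbered pairs of 1 h and of the NF-kB median were chosen after the results had been seen.

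Of 20 prostaglandin and oxidative defence genes, 3 rose, 2 fell and 15 were not called at 24 h (camera adjusted p = 0.310). PTGIS, the prostacyclin synthase, fell from 212 ± 5.49 to 43.9 ± 1.58 CPM and PTGS1 from 42.5 ± 2.29 to 16.0 ± 1.76 CPM, whereas the prostaglandin E2 receptor gene PTGER2 rose from 10.4 ± 1.46 to 30.7 ± 2.64 CPM (edgeR adjusted p = 7.26e-05, 0.00617 and 4.94e-05). PTGS2, the inducible cyclooxygenase gene, was at 30.2 ± 6.29 and 40.8 ± 3.22 CPM and not called. Among immediate early genes, DUSP5 was 3.64-fold and ATF3 4.21-fold higher and KLF4 2.95-fold lower.

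RBM46, GTSF1, TSHR and RNF17 were high in untreated libraries of 24 h alone. RBM46 was at 13.7 ± 0.281 CPM there and had no reads in the other 3 groups, and RNF17 was at 2.15 ± 0.287 CPM there and 0.0914 ± 0.0341 CPM in flagellin libraries of 24 h. HOX genes, chosen as a list after seeing the data, moved both ways at 24 h, 7 higher and 3 lower of 23 tested, where 23.6% of all genes tested were called, with HOXD10 at 3.74 CPM untreated and 28.2 CPM with flagellin and HOXD13 at 1.33 and 0.0719 CPM. None of the 23 was called at 1 h.

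A hypothesis is that the groups of 24 h came from different source cultures. The SD of log2 differences over 10999 genes was 0.601 between untreated and flagellin at 24 h, between 0.390 and 0.540 between numbered pairs of libraries at 1 h, and 0.137 between untreated and flagellin at 1 h. The labels do not say whether the numbered pairs of 1 h were separate cultures, and a shared day or preparation would pair them too. The authors' deposited fit had a term for the source of the cells, so it told sources apart. No label ties a library to a source, so the numbered pairs may be those sources, which was not shown. Genes that differed between those pairs were called at 24 h about as often (24.5%) as other genes (23.8%). Their spread at 1 h enters the estimate of spread over all 12 libraries and makes them harder to call. These shares therefore do not decide between different cultures and a flagellin effect. A fit without the genes that differed between those pairs called 3256 genes. That fit left out 1193 of the 3816 genes by construction, and it called 2604 of the other 2623 and 652 genes not among the 3816. The HOX median of 0.587 lay at percentile 95.7 of random lists, short of the bound set for it. That list was picked after HOXA13 had been seen, and the reading of the test was changed after its value was known, so it decides nothing. Some genes named for 24 h also differed between the numbered pairs of 1 h, alike in both treatments. RPS4XP22 had 90, 1 and 68 reads untreated and 137, 0 and 50 with flagellin in replicates 1 to 3 of 1 h. At 24 h it had 0 to 1 reads per untreated and 79 to 105 per flagellin library. PSG4 and HLA-U also differed between those pairs, whereas RBM46 and GTSF1 had no reads at 1 h. The genes were picked after their values were seen, so they do not decide the question. The hypothesis of different cultures may hold but was not shown. A second hypothesis is a flagellin response through NF-kB at 24 h. The NF-kB list had a median log2 fold change of 0.16 and was not called by camera. Left-out libraries moved it both ways, to 0.33 without untreated replicate 3 and -0.05 without flagellin replicate 2 of 24 h, which leaves it open.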
